A study of Mus musculus with 6 samples.

How the data were processed

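RNA was measured by sequencing in 6 libraries that the labels give as mouse neonatal cardiomyocytes, the name for heart muscle cells from newborn mice. The labels do not say how pure the cells were. Per the labels, 3 libraries are named Ad-scramble and 3 Ad-SPTBN1, the latter with a genotype of raised βII spectrin, the protein encoded by Sptbn1. The labels do not describe the constructs. All 6 carry day 2 in the labels. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made from total RNA with a NEBNext Ultra kit.

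The authors deposited 1 table of FPKM values (fragments scaled by gene length and by the library's total) with 31115 genes and 1 column per library. The GRCm38 and mm10 names of the mouse genome build are given per the submitters' processing notes. The aligner, the counting tool, the annotation release and the use of strand are not given in the sources used here. How reads shared between near-identical genes were counted is therefore unknown, and the values of such genes cannot be judged. Each column was assigned to its library through the sample number in the labels, which equals the column's name. No gene in the table is at 0 in every library. Of the gene IDs, 31065 were found in GENCODE M21, an annotation of the same build.

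Numbers of reads were recovered from the values. With exon lengths from GENCODE M21, 95.6% to 95.7% of the values above 0 in a library were whole numbers of reads within a tolerance of 0.1, and the recovered reads in genes came to 19512434, 18775304 and 19084317 in Ad-scramble replicates 1 to 3 and 19638662, 19472342 and 19017127 in Ad-SPTBN1 replicates 1 to 3. Among tested genes 93.6% to 93.8% of values were whole. The library total by which the FPKM values were scaled came to 18223041 to 19062982 reads. In each library this total was below the recovered reads in genes, so the latter are not the depth itself. The cause of that gap was not tested. Low values are multiples of 1 read, so a gene at few reads carries a large counting error.

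The values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a trend in the prior variance and Benjamini-Hochberg adjustment over the 12608 genes with a mean of at least 1 FPKM. The values were not rescaled. A call is an adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. The labels do not say whether the 3 libraries of a group came from separate cultures or preparations, so the p-values measure the spread between these libraries, which may be technical. No pair of libraries held identical values, and the chi-square per gene, which is 1 for counting noise alone, was 2.79 to 4.25 for pairs within a group.

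A total of 40 gene lists were fixed before the data were examined, as were the main test and the rule for named genes: mitochondrial, metabolic, contractile, cytoskeletal, stress, inflammatory, growth and signalling groups, markers of 8 cell types, and 4 lists that track RNA quality or reference genes. The 38 lists with at least 3 tested members were compared with all other genes by limma's camera with a preset correlation of 0.01, and again with an estimated correlation and with fry. Genes were named by this rule: Sptbn1, then the 12 largest increases and 12 largest decreases among called genes with at least 5 FPKM in the higher group and no overlap between groups, leaving out names of predicted genes (Gm or LOC), RIKEN clones (Rik) and pseudogenes (-ps), a pattern that CT010467.1, named for another kind of clone, passes; and up to 4 called members of each list, or up to 2 of its most abundant members where none was called. A gene named outside the rule is said to be chosen after its values were seen. Some genes that the rule names are not reported here.

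The test was run on simulated reads for the comparison of the 2 groups. Among 12477 simulated genes it recovered 40.3% of genes changed 1.2-fold, 91.0% of those changed 1.5-fold and 98.5% of those changed 2-fold. Of its calls, 1.8% were unchanged genes. The simulated genes were independent and shared the same spread between libraries, so 1.8% need not be the error rate of the real calls. A search for 7-base words in annotated 3′ UTRs, chosen after the data were seen, scored the presence of each word against the log2 difference with UTR length, base composition and expression level as covariates. In 20 trials with a word planted at a log2 difference of -0.05 the search ranked that word first 20 times. The same score was computed for each pair of libraries and each split of the 6 libraries into 3 and 3.

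The alternatives were other pseudocounts, filters, scalings, variance moderation and library weights, the replicate number as a block, and leaving out each library in turn. Added after the data were seen were voom on the recovered reads, a correction for GC content and length, and tests without genes holding the leading 7-mers, without genes that share sequence with another gene, and with a smaller minimum list size. Scripts used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.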

Results

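Gene expression was profiled at day 2 in 3 libraries labelled Ad-scramble and 3 labelled Ad-SPTBN1, all given by the labels as neonatal mouse cardiomyocytes. In the libraries labelled Ad-scramble the cardiomyocyte marker Actc1 measured 21.3 ± 0.405 FPKM and Tnnt2 10.5 ± 0.319, against 2078 ± 152 for the fibroblast marker Col1a1 and 1629 ± 11.6 for the smooth muscle marker Acta2 (SD, n = 3); Col1a1 and Acta2 were chosen after their values were seen. The reads recovered from the FPKM values numbered 19512434, 18775304 and 19084317 in Ad-scramble replicates 1, 2 and 3 and 19638662, 19472342 and 19017127 in Ad-SPTBN1 replicates 1, 2 and 3. The labels do not say that the libraries of a group came from separate cultures, so p-values measure the spread between these samples.

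The comparison of the 2 groups asks, per the labels, how the cells' transcripts differ when βII spectrin, a component of the submembrane skeleton, is raised. Sptbn1 itself went against the label. Sptbn1 (ENSMUSG00000020315, GRCm38 chromosome 11, 30099395 to 30268175, minus strand) measured 50.83, 48.25 and 50.08 FPKM in the libraries labelled Ad-scramble and 16.08, 16.45 and 15.75 FPKM in those labelled Ad-SPTBN1. The level in the libraries labelled as overexpressing was 32.4% of that in the others, a log2 difference of -1.57 ± 0.03 (SE, n = 3 per group, limma adjusted p = 2.72e-06). These values rest on 15381 to 16841 reads against 5086 to 5443. Every direction below is therefore stated for the libraries labelled Ad-SPTBN1 relative to those labelled Ad-scramble, and not for a gain of spectrin.

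**Figure D1:**
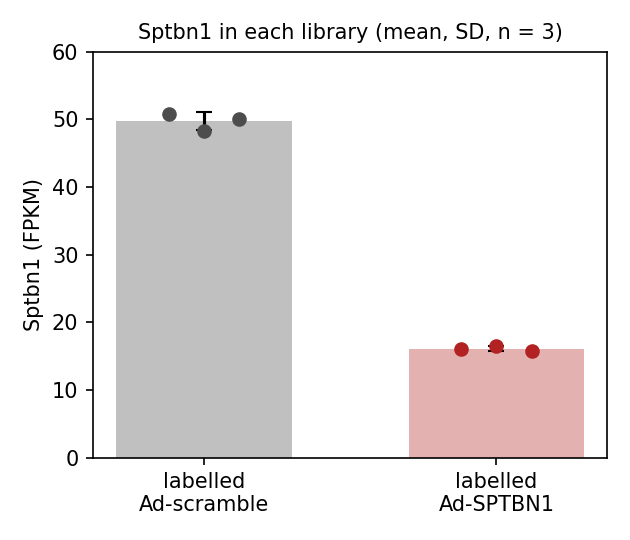
Sptbn1 level in FPKM (vertical axis) in the libraries labelled Ad-scramble and Ad-SPTBN1. Points are single libraries, bars the mean and error bars the SD of 3 libraries; the 3 libraries labelled Ad-SPTBN1 lie between 15.75 and 16.45 FPKM, below all 3 labelled Ad-scramble.

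Many genes differed by small amounts. Of 12608 genes tested with limma, 1391 differed, 698 higher and 693 lower in the libraries labelled Ad-SPTBN1, and 9 of them by at least 2-fold on the log2(FPKM + 1) scale, a count that was 20 with a pseudocount of 0.1 and 3 with a pseudocount of 5. The largest increases were in Lars2, the mitochondrial leucyl-tRNA synthetase, from 1.50 ± 0.103 to 26.2 ± 5.25 FPKM (SD, n = 3), and in the ribosomal RNA gene CT010467.1, from 74.4 ± 4.40 to 393.9 ± 42.4 FPKM. Of the other genes among the 12 largest increases, several are of heart muscle: cardiac actin Actc1 rose from 21.3 ± 0.405 to 46.2 ± 2.27 FPKM, the myosin heavy chain Myh6 from 5.67 ± 0.165 to 11.7 ± 0.834, the natriuretic peptide precursor Nppa from 6.55 ± 0.651 to 12.4 ± 1.57 and the myosin light chain Myl2 from 3.70 ± 0.278 to 6.40 ± 0.912. The tetraspanin Cd81 rose from 74.9 ± 2.03 to 122.3 ± 3.93 FPKM, and Car9, Il11, Fam198b, Sprr1a and Akap1 rose by 0.65 to 0.69 on the log2 scale. The count of 1391 was 622, 864 and 857 without Ad-scramble replicate 1, 2 or 3 and 714, 659 and 655 without Ad-SPTBN1 replicate 1, 2 or 3. CT010467.1 shares 48.6% of its 50-base words with another gene and overlaps 2 other annotated genes, Myh6 shares 22.6%, and 61.5% of Nppa's exon bases lie opposite an antisense gene, so their values are uncertain. The transcripts of Lars2 and Gm15564, a transcript similar to ribosomal RNA, share 22 words of 31 bases, and Gm15564, chosen after its values were seen, measured 1.14 ± 0.0598 and 3.46 ± 0.221 FPKM, so the value of Lars2 is uncertain too. How much ribosomal RNA each library kept was not measured separately. The rises of CT010467.1 and Lars2 therefore need not be changes of expression in the cells.

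After Sptbn1, the largest decreases were in the lipid kinase Pip4k2a, from 21.7 ± 1.91 to 12.1 ± 0.823 FPKM, and in Fxyd6, a regulator of the sodium pump, from 28.6 ± 0.681 to 16.5 ± 0.827. Chmp2b, a subunit of the ESCRT-III membrane complex, fell from 26.6 ± 1.55 to 16.1 ± 1.34 FPKM and the caveolin Cav2 from 10.99 ± 0.734 to 6.66 ± 0.660. Fam120a fell from 59.7 ± 1.27 to 39.0 ± 0.815 FPKM, and Cd99l2, Fgl2, Vegfd, Rgs19, Chsy3 and Tmem50b fell by 0.63 to 0.66 on the log2 scale. Each of the 12 decreases, Sptbn1 included, and the 12 increases had an adjusted p of 0.00824 or less and held when any 1 library was left out.

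Genes of the respiratory chain, which the title of the series names, showed few calls. These genes were measured in all cells of the cultures together. In the libraries labelled Ad-scramble the fibroblast marker Col1a1 was at 2078 FPKM and the cardiomyocyte marker Actc1 at 21.3 FPKM. The values below can therefore not be assigned to cardiomyocytes. Of 36 nuclear complex I subunits 0 were called, and adjusted over the list alone 0 were called; Ndufa2 measured 84.0 ± 3.42 and 81.2 ± 1.99 FPKM and Ndufa1 54.7 ± 1.61 and 59.3 ± 5.54 FPKM in the libraries labelled Ad-scramble and Ad-SPTBN1. Over all 12608 tested genes, and not these subunits alone, 3394 had an unadjusted limma p under 0.05, which is not a call. Among 42 subunits of complexes II to V, 0 rose and 2 fell (1 adjusted over the list alone). Cox6b1 went from 131.6 ± 4.85 to 93.8 ± 10.5 FPKM, and Atp5j2 fell by 0.13 on the log2 scale. Of 13 subunits encoded in mitochondrial DNA 1 fell (1 adjusted over the list alone), mt-Nd3, which shares 98.0% of its 50-base words with other genes. How shared reads were counted is not known, so subunits with near-identical copies cannot be judged, whether called or not. The TCA cycle list had 2 of 24 lower (2 adjusted over the list alone): Sucla2 fell by 0.44 and Idh2 fell by 0.23 on the log2 scale. Fatty acid oxidation had 3 of 26 higher and 2 lower (6 and 5 adjusted over the list alone), with Angptl4 higher and Echs1 lower. Mitochondrial biogenesis and dynamics had 2 of 33 lower (1 adjusted over the list alone), Fis1 and Slc25a4. The mitochondrial ribosome had 1 of 79 higher, Mrpl3, and 1 lower, Mrpl58 (0 adjusted over the list alone). None of these 7 lists was called as a set by camera (adjusted p between 0.194 and 0.785) or by fry for a shared direction (0.0798 to 0.788). The mixed test of fry asks whether members change in either direction, and not whether they differ from other genes. It passed for the TCA cycle (adjusted p = 2.06e-06), fatty acid oxidation (4.6e-05) and the mitochondrial ribosome (0.000102). Biogenesis and dynamics (0.00218) and complexes II to V (0.00224) passed too. Complex I (0.245) and the subunits encoded in mitochondrial DNA (0.41) did not, while the reference genes did (0.000249). The calls on Atp5j2 and Slc25a4 were lost without any 1 of the 6 libraries (adjusted p from 0.0749 to 0.141 and from 0.0525 to 0.12). That on mt-Nd3 was lost without any but Ad-scramble replicate 1 (0.058 to 0.0773), and that on Mrpl3 without any but Ad-SPTBN1 replicate 1 (0.0626 to 0.0756). The call on Idh2 was lost without any but Ad-scramble replicate 1 and Ad-SPTBN1 replicate 2 (0.0831 to 0.0921). That on Angptl4 was lost without any but replicate 3 of each group (0.0752 to 0.085), and that on Mrpl58 without any but replicate 2 of each group (0.0506 to 0.0621). The call on Echs1 was lost without Ad-SPTBN1 replicate 1 (0.0565) or 2 (0.0599).

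The lists of cardiomyocyte markers and sarcomere genes were called higher by camera, and 3 other lists of heart genes were not. Of 10 tested cardiomyocyte markers 7 rose and 0 fell (10 rose adjusted over the list alone). The smallest p were in Actc1, Myh6, Tnnt2 and Mybpc3. The fixed list holds 15 markers, and those with a mean under 1 FPKM were not tested. In the libraries labelled Ad-scramble and Ad-SPTBN1, Ryr2 measured 0.554 and 0.638 FPKM, Myh7 0.280 and 0.597, and Pln 0.424 and 0.418. Ckm measured 0.314 and 0.456 FPKM and Ttn 0.0871 and 0.175. These untested markers were named after their values were seen. For the tested markers, camera adjusted p was 2.57e-09 with the preset and 0.0499 with an estimated correlation. The latter call rests on the family of lists. Over the 39 lists with at least 1 tested member, the smallest camera adjusted p with an estimated correlation was 0.0512. That family was chosen after the data were seen, and its values were computed before those of the 38 lists. Of 22 sarcomere genes, 7 rose and 0 fell (9 and 1 adjusted over the list alone), with adjusted p = 4.36e-05 and adjusted p = 0.134 with an estimated correlation; 9 of the 22, and 6 of the 7 that rose, are also on the list of cardiomyocyte markers. Tnnt2 rose from 10.5 ± 0.319 to 13.9 ± 0.0743 FPKM, while the atrial light chain Myl7 measured 23.7 ± 1.89 and 26.3 ± 1.49 FPKM and did not pass (adjusted p = 0.193); Myl7 was chosen after its values were seen. Calcium handling genes had 2 of 24 higher, with Casq2, and 2 lower, with Cacna1g (2 and 3 adjusted over the list alone; camera adjusted p = 0.257; not called as a set by camera). Nor was the intercalated disc (0 of 15, and 0 adjusted over the list alone; Itgb1 407 ± 13.9 and 417 ± 5.55 FPKM; adjusted p = 0.342). The hypertrophy markers (5 of 22 higher, 1 lower; 7 and 2 adjusted over the list alone; camera adjusted p = 0.333) were not called as a set by camera. By fry, which tests whether a list's genes move on balance one way and not whether they differ from other genes, the calcium handling list (adjusted p = 0.00484) and the hypertrophy list (adjusted p = 0.0332) passed. Among them, Timp1 and Ankrd1 rose by 0.31 and 0.16. The call on Casq2 was lost without any library but Ad-scramble replicate 2 (adjusted p from 0.0714 to 0.116) and that on Cacna1g without any but Ad-SPTBN1 replicate 3 (0.0702 to 0.114).

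Markers of other cell types were abundant and moved as well. The collagen gene Col1a1 measured 2078 ± 152 and 2402 ± 103 FPKM and Acta2 1629 ± 11.6 and 1604 ± 15.9 FPKM, above the 46.2 FPKM of Actc1; neither passed the test (adjusted p = 0.056 and 0.558). Of 15 cardiac fibroblast markers 1 rose and 8 fell (2 and 9 adjusted over the list alone; adjusted p = 0.000272, and adjusted p = 0.0629 with an estimated correlation). Dpt went from 80.6 ± 5.15 to 62.2 ± 2.42 FPKM, and Gsn and Mfap5 also fell. Of 13 smooth muscle and pericyte markers 1 rose, Cspg4, and 6 fell (1 and 10 adjusted over the list alone), with Mylk and Notch3 lower; adjusted p was 5.67e-05, and adjusted p was 0.0629 with an estimated correlation. Of 10 epicardial and mesothelial markers 5 rose and 0 fell (6 adjusted over the list alone; adjusted p = 0.00016, and adjusted p = 0.0629 with an estimated correlation). Krt18 rose from 40.3 ± 1.58 to 53.04 ± 1.61 FPKM, and Msln, from 4.03 ± 0.448 to 6.55 ± 0.668. Endothelial markers (0 of 15, and 0 adjusted over the list alone, adjusted p = 0.785; Eng 90.4 ± 2.82 and 96.9 ± 2.67 FPKM) were not called. Macrophage markers (0 of 4, and 0 adjusted over the list alone, with a median of -0.004 and a mean of 0.023 on the log2 scale, adjusted p = 0.985; Lyz2 4.65 ± 0.112 and 4.45 ± 0.647 FPKM) were not called. Schwann cell markers had 2 tested members and erythroid markers 0, below the minimum of 3.

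**Figure D2:**
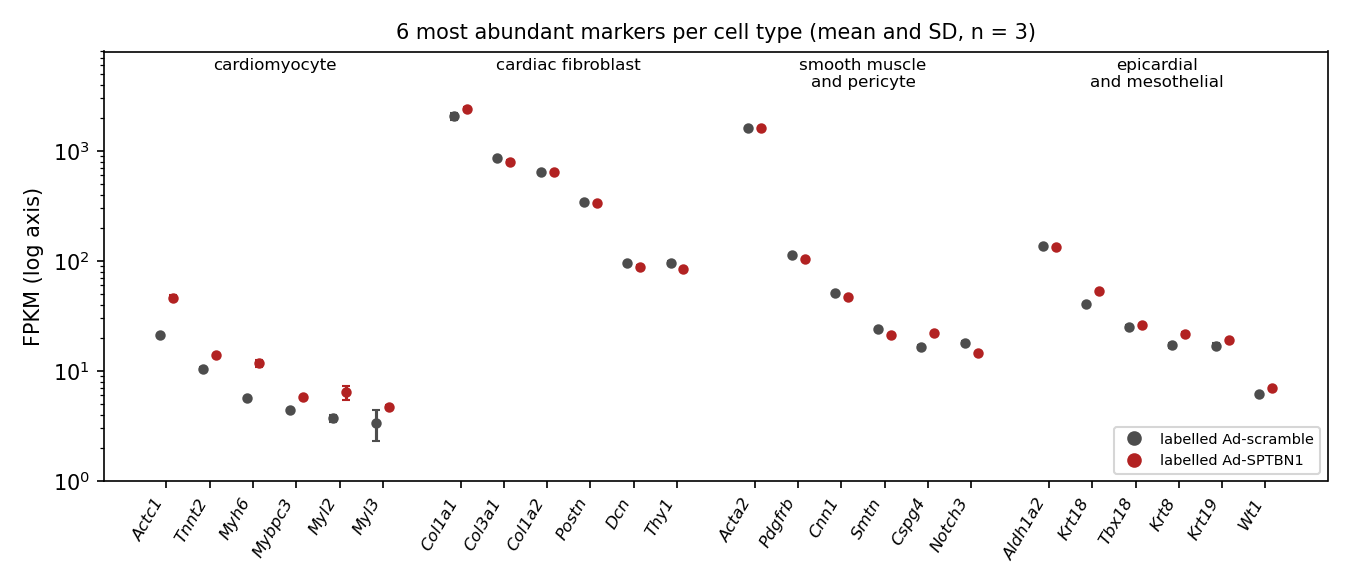
Levels in FPKM (vertical log axis) of the 6 most abundant markers of 4 cell types in the libraries labelled Ad-scramble and Ad-SPTBN1, as mean and SD of 3 libraries. Actc1 lies at 21.3 and 46.2 FPKM, and Col1a1 at 2078 and 2402 FPKM.

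The lists of the integrated stress response and of p53 targets were called higher, and the cell cycle list lower. In the integrated stress response list, 15 of 31 genes rose and 0 fell (20 and 2 adjusted over the list alone; adjusted p = 2.57e-09, and adjusted p = 0.0629 with an estimated correlation). Sesn2 rose from 51.7 ± 2.20 to 72.5 ± 2.38 FPKM, and the amino acid transporters Slc7a1 and Slc7a5 and asparagine synthetase Asns rose as well. In the p53 and apoptosis list, 12 of 30 rose and 3 fell (14 and 5 adjusted over the list alone; adjusted p = 0.000313, and adjusted p = 0.0629 with an estimated correlation). The cell cycle inhibitor Cdkn1a rose from 199.8 ± 6.28 to 298.8 ± 5.88 FPKM, and Ccng1, Mdm2 and Aen also rose. Of 46 cell cycle genes 0 rose and 13 fell (2 and 19 adjusted over the list alone; adjusted p = 1.21e-09, and adjusted p = 0.0499 with an estimated correlation). As for the cardiomyocyte markers, the call with an estimated correlation ended (0.0512) over the 39 lists with at least 1 tested member, computed first. Mki67 went from 13.4 ± 0.818 to 10.5 ± 0.180 FPKM, and Ube2c and Cdk1 also fell. The list made for replication-dependent histones had 0 of 23 higher and 4 lower (the same adjusted over the list alone; adjusted p = 0.0229, and adjusted p = 0.134 with an estimated correlation); H1f0, which encodes a linker histone whose expression does not depend on replication, fell by 0.24, and Hist1h1c fell by 0.30. Ube2c has 22.8% of its exon bases opposite Tnnc2. The histone call was lost without Ad-scramble replicate 1 (adjusted p = 0.0542) or 2 (0.0587), and with voom on the recovered reads (0.0797), chosen after the data were seen.

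The inflammatory list was called higher in the libraries labelled Ad-SPTBN1, with 13 of 32 members up and 3 down, and the same counts adjusted over the list alone (adjusted p = 0.000239, and adjusted p = 0.0629 with an estimated correlation). The chemokine Cxcl5 rose from 36.0 ± 1.66 to 55.7 ± 2.88 FPKM, and the adhesion molecules Icam1 and Vcam1 rose by 0.23 and 0.25. Interferon-stimulated genes, which respond to viral nucleic acids, had 1 of 44 higher, Bst2, and 2 lower, Cxcl10 and Iigp1 (0 and 2 adjusted over the list alone; adjusted p = 0.342). The call on Bst2 was lost without any library but Ad-scramble replicate 2 (adjusted p from 0.108 to 0.125) and that on Iigp1 without Ad-scramble replicate 1 or Ad-SPTBN1 replicate 2 or 3 (0.0547 to 0.0573). The list of immediate early genes was called lower, with 1 of 25 members up and 13 down (1 and 16 adjusted over the list alone; adjusted p = 1.68e-05, and adjusted p = 0.294 with an estimated correlation); Fos went from 273.6 ± 4.08 to 220.4 ± 2.00 FPKM and Fosb from 188.1 ± 5.93 to 150.7 ± 4.86. The hypoxia list had 5 of 22 higher and 0 lower (7 and 0 adjusted over the list alone), with Car9 and Ero1l (adjusted p = 0.0327, and adjusted p = 0.149 with an estimated correlation). Glycolysis had 4 of 20 higher and 0 lower (5 and 0 adjusted over the list alone), with Gpi1 up by 0.26 (adjusted p = 0.0229, and adjusted p = 0.206 with an estimated correlation). Both calls were lost without Ad-scramble replicate 1 (adjusted p = 0.066 and 0.0619) and without Ad-SPTBN1 replicate 1 (0.0712 for each), and with a minimum mean of 5 FPKM (0.0759 and 0.0563). Glycolysis was also lost without genes that share over 20% of their 50-base words with another gene (adjusted p = 0.128), a test chosen after the data were seen. The hypoxia and glycolysis lists share Slc2a1 and Hk2, called higher, and Ldha and Pfkfb3, not called, so their calls are not independent. The calls on Slc2a1 and Hk2 were lost without any library but Ad-scramble replicates 2 and 3 (adjusted p from 0.0577 to 0.0784).

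The lists of the extracellular matrix, TGF-β targets and cholesterol synthesis were called lower, in the same libraries in which 8 of 15 fibroblast markers and 6 of 13 smooth muscle and pericyte markers fell. The matrix list shares 6 of its 40 tested members with the fibroblast markers, of which 2 fell, and the TGF-β list shares 3 of 32, of which 1 fell. Of 40 extracellular matrix genes 3 rose and 13 fell (5 and 18 adjusted over the list alone; adjusted p = 0.00076, and adjusted p = 0.11 with an estimated correlation). Elastin Eln went from 512.1 ± 36.1 to 371.7 ± 7.60 FPKM, while tenascin Tnc rose from 243.3 ± 5.63 to 323.3 ± 0.130. TGF-β targets had 4 of 32 higher and 8 lower (5 and 11 adjusted over the list alone; adjusted p = 0.0209, and adjusted p = 0.227 with an estimated correlation), with Il11 higher; Tgfb3 fell by 0.39 and Tgfbi fell by 0.27. That call was lost without Ad-SPTBN1 replicate 1 (adjusted p = 0.0793) and with quantile normalization (0.0596). Of 21 cholesterol synthesis genes 0 rose and 6 fell (12 adjusted over the list alone; adjusted p = 0.000268, and adjusted p = 0.122 with an estimated correlation) and Cyp51 fell by 0.22. In the membrane skeleton list, 3 of 18 rose and 1 fell (3 and 4 adjusted over the list alone; adjusted p = 0.284): vinculin Vcl went from 78.9 ± 0.227 to 52.7 ± 1.10 FPKM, and Flnc rose from 21.6 ± 0.242 to 25.7 ± 0.480. The membrane skeleton list was called lower (adjusted p = 0.0145) without genes whose 3′ UTR holds GATGCAA or GTGTCAC. The actin and microtubule list was called lower (adjusted p = 0.0466) without genes that share over 20% of their 50-base words. Both tests were chosen after the data were seen and used the preset correlation. With an estimated correlation over all tested genes, camera adjusted p was 0.732 and 0.349 for these lists. Vcl has 25.5% of its exon bases opposite Ap3m1, and Stmn1 shares 36.5% of its 50-base words with other genes. Actin and microtubule genes (1 of 30 higher, 6 lower, 3 and 7 adjusted over the list alone, with Myh10 and Stmn1 down; camera adjusted p = 0.194) were not called as a set by camera. Nor were antioxidant genes (0 of 28 higher, 4 lower, 0 and 5 adjusted over the list alone, with Gpx3 down; camera adjusted p = 0.124) or autophagy (3 of 30 higher, 0 lower, 4 and 4 adjusted over the list alone, with Atg12 up; adjusted p = 0.677). Endoplasmic reticulum chaperones (2 of 22 higher, 1 lower, 3 and 1 adjusted over the list alone, with Ern1 up; adjusted p = 0.302) and heat shock genes (1 of 20 higher, Hspa9, and 1 adjusted over the list alone; adjusted p = 0.785) were not called as sets. By fry, both the actin and microtubule list and the antioxidant list passed (adjusted p = 0.0146 for each). The call on Gpx3 was lost without Ad-scramble replicate 1 or Ad-SPTBN1 replicate 2 or 3 (adjusted p from 0.0631 to 0.0658) and that on Ern1 without any but Ad-scramble replicate 2 and Ad-SPTBN1 replicate 1 (0.0587 to 0.0679).

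**Figure D3:**
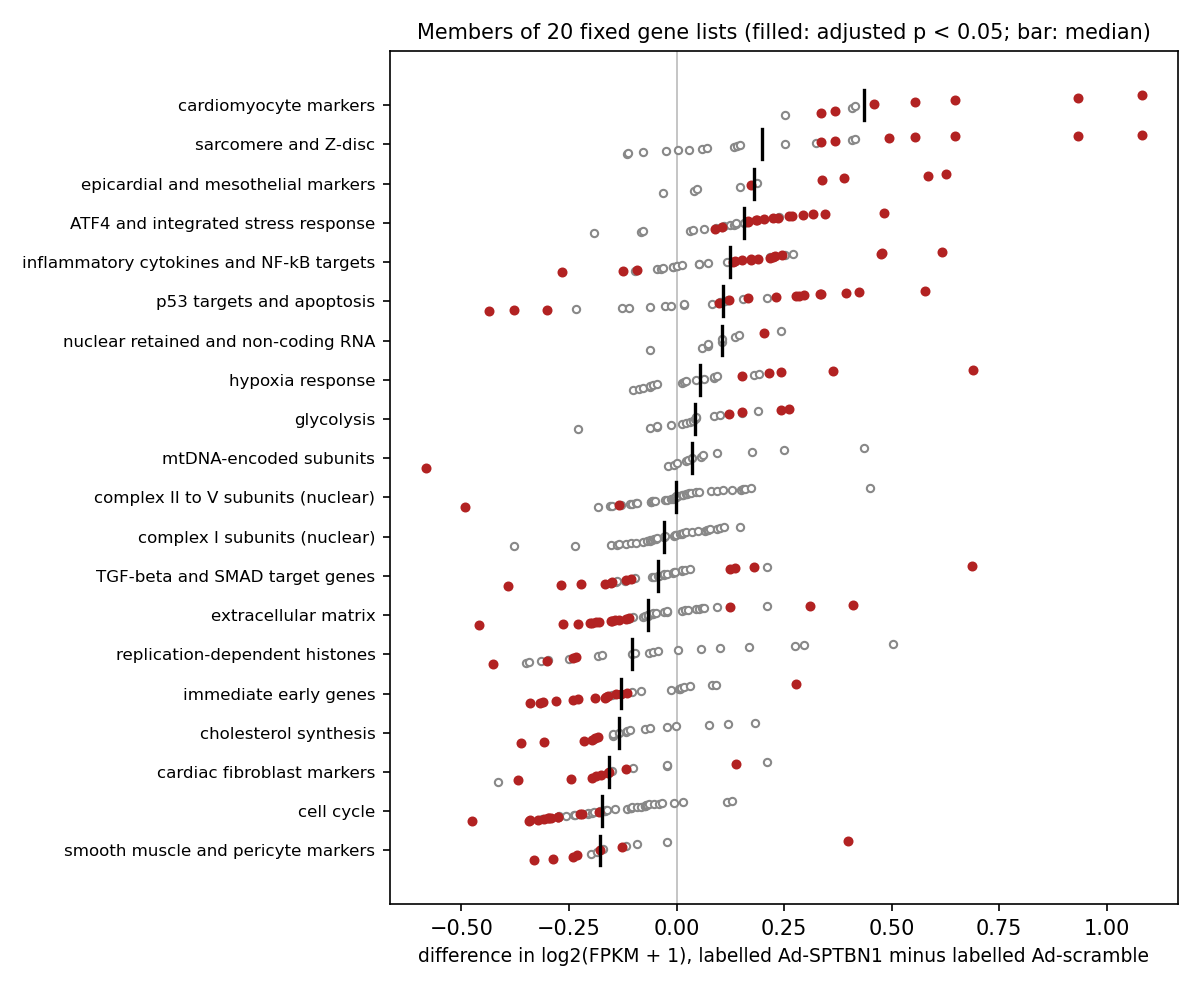
Difference in log2(FPKM + 1), labelled Ad-SPTBN1 minus labelled Ad-scramble (horizontal axis), of each tested member of 20 fixed lists; filled points passed an adjusted p of 0.05 and bars are medians. Cardiomyocyte markers have a median of 0.44 and cell cycle genes one of -0.17, while complex I subunits have a median of -0.03.

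Of the lists that track RNA quality, nuclear and non-coding RNA was called higher with 1 of 10 members past the threshold, Snhg1 (2 adjusted over the list alone; adjusted p = 0.014, and adjusted p = 0.134 with an estimated correlation). Cytosolic ribosomal proteins had 1 of 82 higher and 3 lower (0 adjusted over the list alone; adjusted p = 0.677), and the reference genes 2 of 15 higher, Tfrc and Polr2a (3 higher and 1 lower adjusted over the list alone; adjusted p = 0.475). The call on Snhg1 was lost without Ad-scramble replicate 1 (adjusted p = 0.0526) or Ad-SPTBN1 replicate 1 (0.0506), and that on Polr2a without any library but Ad-scramble replicate 1 (0.0709 to 0.117). In all, 17 of 38 lists were called by camera with the preset correlation. Only cardiomyocyte markers and cell cycle genes stayed called with an estimated correlation (adjusted p = 0.0499 for each). Neither did over the 39 lists with at least 1 tested member (smallest adjusted p = 0.0512).

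Sequence in the 3′ UTR went with the direction of change, in a search chosen after the data were seen. Among 11091 genes and 15612 words of 7 bases, GATGCAA led the genes lower in the libraries labelled Ad-SPTBN1 (z = -11.9) and GTGTCAC led the genes higher (z = 16.5); the highest absolute z in 1000 permutations of the genes was 5.19. Between libraries of the same group the largest absolute z was 3.5 to 4.3, with other words. The 9 splits that mix the groups gave a largest absolute z of 8.3 to 10.8, with GTGTCAC leading in each; such splits keep part of the difference between the groups. The 731 genes holding GATGCAA differed from genes without it by a mean of -0.06 on the log2 scale, and the 1176 genes holding GTGTCAC were higher by 0.073. GTGTCAC was present in 30.3% of the 650 higher genes searched, 6.9% of the 651 lower genes and 9.5% of the genes not called. GATGCAA was present in 18.7% of lower, 5.5% of higher and 5.9% of genes not called. Fxyd6, Chmp2b, Cav2, Rgs19, Chsy3, Tmem50b, Fam120a and Cox6b1 hold GATGCAA, and Nppa, Cd81 and Fam198b hold GTGTCAC. Against the trend, Chmp2b, Cd99l2, Sptbn1 and Tpm2, all lower, also hold GTGTCAC, and Slc7a1, Atg12 and Ern1, which rose, hold both words. The call on Tpm2 was lost without Ad-SPTBN1 replicate 1, 2 or 3 (adjusted p from 0.0578 to 0.0683).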

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

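Most alternatives were chosen before the data were examined; voom, the GC and length correction, the 2 tests on fewer genes and the smaller list minimum were chosen after. The Sptbn1 log2 fold change stayed past the threshold under every alternative run, between -1.63 and -1.38. No named gene or list with a call changed direction. Over all scalings the median log2 difference of all genes was at most 0.0087. The number of different genes was 665 (334 higher, 331 lower) with no filter on low values, where 31115 genes were tested, and 2145 (1087 and 1058) with voom on the recovered reads, 1312 of them shared with the 1391; the cause of the latter was not tested. With the genes whose 3′ UTR holds either leading 7-mer taken out it was 838 (392 and 446). Of the 1391 called genes 372 hold a 7-mer, 930 were searched and hold none, and 89 had no searched 3′ UTR. Of the 1019 without a known 7-mer, 909 were left when p-values were adjusted over the remaining 10848 genes. When those genes were also fitted anew, 838 were left. Leaving out 1 library gave 622 to 864 different genes, 302 to 441 higher and 320 to 438 lower, with fewer samples in each fit, and 44 of the 127 named genes past the threshold lost their call in at least 1 of these fits. No pairing of the libraries by replicate number was visible. The correlations of the deviations of same-numbered libraries were 0.006, -0.034 and 0.01, and not every library correlated best with its own number. These correlations cannot show whether same-numbered libraries were prepared together. With the replicate number as a block the count was 730 (369 higher, 361 lower). The 9 genes changed at least 2-fold became 20 with a pseudocount of 0.1, 3 with a pseudocount of 5, 4 with a minimum mean of 5 FPKM, 19 after rescaling to equal sums and 19 with voom, so this count depends on the scale. Of the 17 lists called with a preset correlation, 2 held with an estimated one, cardiomyocyte markers and cell cycle genes, at an adjusted p of 0.0499, next to the threshold; when the 39 lists with at least 1 tested member were adjusted together, 0 held and the smallest adjusted p was 0.0512. Depth limits the genes under 1 FPKM, which were tested in the fit with no filter only.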

Other observations

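In this part, the tests of Sptbn1, of the 3′ UTR words and their splits and of the spread of cardiomyocyte markers were chosen after the results were seen, and those of sites in the markers, of calls without site-bearing genes and of GC content and length after the data were seen; Gm15564, Gm26917, mt-Rnr1 and Mgp were chosen after their values were seen. Of the ribosomal-RNA-like transcripts, Gm15564 measured 1.14 ± 0.0598 and 3.46 ± 0.221 FPKM in the libraries labelled Ad-scramble and Ad-SPTBN1, Gm26917 51.1 ± 7.43 and 60.2 ± 6.54 FPKM, and mt-Rnr1 315.9 ± 10.4 and 317.8 ± 21.2 FPKM. The transcripts of Gm15564 and Lars2 share 22 words of 31 bases, and Lars2 and CT010467.1 share 0. Matrix Gla protein Mgp measured 346.6 ± 14.0 and 229.5 ± 7.58 FPKM.

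Sptbn1 was lower in the libraries labelled as overexpressing it, and the 3′ UTR words may point to short hairpin RNAs in both constructs, a hypothesis found and tested on the same data. A cDNA alone was taken to bring about no leading 3′ UTR word, a premise that was not tested. On that premise, the z of 16.5 argues against swapped labels with a cDNA alone as the construct. Whether a cDNA was also present was not tested either. RNA interference with a guide against Sptbn1 and a control guide predicts what was seen for the lower genes (z = -11.9), with site effects graded from a mean of -0.1 for GATGCAAA to 0.001 for the 6-base site, and the words leading in 1 random group of genes scored -8.4 and 12.9 in the remaining genes. GATGCAA occurs once in the Sptbn1 coding sequence (exon 19, GRCm38 chromosome 11, 30123930 to 30123936), which is weak evidence because 38.1% of scored words occur in that transcript; GTGTCAC lies at bases 11 to 17 of TTCTCCGAACGTGTCACGT, a widely used non-targeting control recalled from general knowledge, but the word 1 base further on, TGTCACG, which a guide made from the full 19 bases would favour, had a z of 2.7 only. The construct sequences are not in the sources used here. Of 10 splits of the 6 libraries, too few for a share under 0.05, only the real grouping gave a z of 16.5 (the highest other 10.8).

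Cardiomyocyte markers were higher in the libraries labelled Ad-SPTBN1. A larger share of uniform cardiomyocytes as the whole cause would raise all 10 tested markers alike, if no other cells expressed them. Expression of the markers in other cells was not measured, so unequal ratios cannot decide on that cause. The SD of the markers' log2 read ratios was 0.26, only just above the bound of 0.251 set as 2 times the median standard error. A weighted statistic was therefore added after that result. The markers' squared deviations in standard errors summed to 164.7 on 9 degrees of freedom, with Actc1 at 1.12 ± 0.06 and Tnnt2 at 0.40 ± 0.04 (SE). The tested markers thus did not rise alike. Sites of a control guide, if there is one, in the markers are argued against, since 0 of 10 hold GTGTCAC. A share that differs, alone or together with a change inside the cells, stays open, and which of these holds was not tested.

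The number of different genes could come from direct sites of guides, if the constructs hold any, or from a bias of GC content or length. Of the 1391 called genes, 372 held a word, 930 had a searched 3′ UTR without one and 89 had none that was searched, and when the genes with a word were taken out and the others fitted and adjusted anew, 838 were called, 767 of them searched, so direct 3′ UTR sites of these 7 bases are not the whole source, although 21.1% of the genes with a word were called against 10.0% of those without. After correction for GC content and length 1614 genes were called. In 10 splits of the libraries, too few for a share under 0.05, only the real grouping gave 1391 different genes (the highest other 1). It alone also gave 9 genes changed at least 2-fold (the highest other 1) and 17 lists (the highest other 8). Effects downstream of Sptbn1 and indirect effects of the constructs stay open, and the design cannot separate them because each group holds 1 construct.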
